A study of Arabidopsis thaliana with 6 samples.

How the data were processed

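RNA from rosettes of 2 week old Arabidopsis thaliana Col-0 plants was compared on 6 two-colour Agilent arrays, 3 for the PIP1 peptide and 3 for the PIP2 peptide. Each array set RNA of plants sprayed for 3 h with 100 nM peptide in 0.02% Silwet L-77, a wetting agent, against RNA of plants sprayed with water and Silwet. In both groups the peptide RNA of replicate 1 was in Cy5 and that of replicates 2 and 3 in Cy3. Replicates 1 and 2 of both peptides lay on slide 1 and replicate 3 on slide 2, as the array identifiers show. The labels call the replicates biological, and their extract protocol speaks of more of them than the 3 arrays per peptide used here. The labels do not say whether they came from separate sowings or whether the arrays of one number shared a water RNA, so p-values measure the spread between these arrays, which may be partly technical.

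The scanner files hold spot intensity values on a linear scale, extracted with Agilent Feature Extraction 9.5.1.1 per the file headers. The deposited value table holds log2 ratios, whose processing is named only as limma in R 3.0.3 per the submitters' processing notes, with no limma version and no model. Set against the scanner values, the deposited log2 ratios ran in the direction peptide over water, with correlations across probes from 0.873 to 0.995 and slopes from 0.986 to 1.36. Their medians were 0.0091, -0.0019 and 0.0174 for PIP1 replicates 1 to 3, and 0.0069, -0.00915 and 0.0095 for PIP2, and how they were centred stays unknown. The table was used only as an alternative.

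Mean spot intensities were background-corrected with normexp (offset 50), normalized within each array by loess with span 0.3 and control spots at weight 0, and the average intensities were equalised between arrays (Aquantile) in limma 3.58.1 under R 4.3.3. Plots were drawn in matplotlib 3.10.9 under Python 3.11.15. Control spots and spots marked as outliers by the scanner software were left out, and spots of one probe were averaged. A probe was kept where either channel was well above background on at least 3 arrays. Of 43603 probes, 30926 passed, and the probe with the highest mean intensity stood for each gene, which gave 23337 genes tested, 20881 with a locus and 2456 known only by probe. The array design names 38413 probes by locus and 5190 by none, and 873 probes list more than 1 locus. Symbols came from a reference table of assembly TAIR10.1 for 37943 probes, while 470 kept the file's name; the array's own annotation is older, so no coordinates are given.

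Log2 ratios of peptide over water were fitted with lmFit and eBayes on all 6 arrays together, with a term for dye orientation. The dye term was shared by both peptides, so a peptide's coefficient and standard error also drew on the other peptide's arrays. Replicate 1 weighed more in it than replicate 2 or replicate 3. In the mean of both peptides, replicate 1 carried as much weight as replicates 2 and 3 together. The contrasts were PIP1 against water, PIP2 against water, PIP1 minus PIP2 and the mean of both peptides, each with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. In all, 23 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives. Groups, contrasts, lists, most alternatives and the rule for naming genes were set before the data were examined. The rule named the PIP1 and PIP2 precursor genes and RLK7, the 10 highest and 10 lowest called genes of a contrast with one sign on each of its arrays, the 5 genes of smallest p per direction where none was called, and up to 3 called members per list and direction. The genes of smallest p also needed one sign, which for PIP1 minus PIP2 meant one sign in each same-numbered pair. One sign was thus a condition of such naming and not a result. Other list members are named below for description and were chosen after their values were seen.

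Same-numbered arrays of the peptides deviated together from their group means, with correlations of 0.713, 0.855 and 0.757 for the 3 numbers and no dye term. Replicate 1 also differed from the others in dye and replicate 3 in slide. Whether this pairing of the arrays came from the RNA, the dye or the slide can therefore not be told apart. Because of the pairing, the replicate number was also fitted as a block and, with the dye term, as a random effect (consensus correlation 0.701). The fits were tested on simulated data of 23337 genes with 200 changed. At a replicate correlation of 0.7 the fit used here recovered 96% of PIP1 changes of log2 1, with 44 false calls of 240, and made 229 false calls of 427 for the mean of both peptides. The random effect made 36 false calls of 232 for the mean. With no gene changed, the block made 274 false calls for PIP1, 230 for PIP2, 2977 for the mean and 0 for PIP1 minus PIP2. Its counts against water are therefore too high, and only its test of the difference held in simulation. With 200 genes differing between the peptides, the block and the random effect called 198 and 196. On the measured arrays they called 580 and 0, so the simulation did not reproduce this disagreement.

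Between 62.4% and 67.8% of probes were well above background in a channel on slide 1 and between 90.8% and 95.2% on slide 2. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.10 for either peptide, 0.14 for the difference and 0.07 for the mean.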

Results

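Gene expression in Arabidopsis rosettes was measured 3 h after spraying with PIP1 or PIP2, secreted peptides that the series title places among negative modulators of immunity. Each peptide was set against water on 3 arrays, and 23337 genes were tested. The standard deviation of the log2 ratios over genes lay between 0.26 and 0.40 on the PIP1 arrays and between 0.40 and 0.49 on the PIP2 arrays. The comparisons ask which genes each peptide changed, whether the peptides differed, and what they shared.

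With PIP1, several jasmonate response genes rose. The transcription factor gene ANAC055 was 4.58-fold higher than with water (SE 0.16 on the log2 scale, n = 3 arrays, limma adjusted p = 0.037), and JAZ7, a repressor of jasmonate signalling, 4-fold higher (log2 2.00 ± 0.20, adjusted p = 0.041). CYP94C1, which oxidises the active jasmonate, rose by log2 1.98 ± 0.20, and the repressor genes JAZ9 and JAZ10 rose by 1.67 ± 0.11 and 1.59 ± 0.09. Among genes that fell, WRKY60 fell by 1.31 ± 0.13 on the log2 scale, UGT76B1 fell by 1.19 ± 0.10, and MLO12 fell by 1.16 ± 0.09. The endoplasmic reticulum chaperone genes CNX1 and BIP2 fell by 1.05 ± 0.09 and fell by 0.93 ± 0.10, each on 3 of 3 arrays, as the naming rule required. Second probes of several of these genes stood closer to 0 and did not pass, at -0.25 for BIP2 (limma adjusted p = 0.696), -0.22 for UGT76B1 (adjusted p = 0.317), -0.61 for MLO12 (adjusted p = 0.194) and -0.78 for CNX1 (adjusted p = 0.166), in a fit of every probe separately that called 0 genes with PIP1.

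ANAC072, ROXY19, AT2G32150, AT2G20670 and AT5G55970 completed the 10 largest rises with PIP1, at log2 values from 1.49 for ROXY19 to 1.75 for ANAC072, and a second ROXY19 probe stood at 0.41. AT1G04770, AT3G47380, AT2G39518, EXO70H2 and the proton pump gene HA2 completed the 10 largest falls, from -1.13 for AT1G04770 to -0.92 for HA2. Of the 39 measured members of the jasmonate list, 11 rose and 0 fell, and 24 rose and 1 fell when adjusted over the list alone. The list passed camera upwards (adjusted p = 8.86e-20), with an estimated correlation (adjusted p = 0.0414) and in fry (adjusted p = 0.00301). With the replicate block fitted it no longer passed with an estimated correlation, where 0 lists did. The sugar starvation list had a median of 0.95, with 1 of 10 members called, TPS8 at 1.43 ± 0.10. It passed camera (adjusted p = 1.93e-10) and fry (adjusted p = 0.0242) but not camera with an estimated correlation (adjusted p = 0.273). The iron list passed downwards in camera (adjusted p = 0.0248) and fry (adjusted p = 0.0349), with 0 of 15 members called and adjusted p = 0.459 with an estimated correlation. The cold and touch response list passed upwards in camera (adjusted p = 0.00518) and fry (adjusted p = 0.0242), with 0 of 10 members called and adjusted p = 0.325 with an estimated correlation. Camera alone placed the heat shock, abscisic acid, clock, aliphatic glucosinolate and oxidative stress lists upwards and the salicylic acid list downwards, with fry adjusted p from 0.120 to 0.498 and adjusted p from 0.459 to 0.688 with an estimated correlation. The heat shock list medians with PIP1 were 0.83, 0.05 and 0.83 on replicates 1 to 3.

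Altogether 89 genes changed with PIP1, 68 higher and 21 lower, and 36 of the higher and 7 of the lower by at least 2-fold. Leaving out any 1 of the 6 arrays left 0 called genes, with 1578 to 3373 at an unadjusted p under 0.05. The replicate block called 6461 genes, a count that simulation showed to be inflated, and the random replicate effect called 29. With that effect 10 of the 20 genes named as the largest changes were no longer called, among them JAZ7 (adjusted p = 0.0821), ANAC072 (adjusted p = 0.0708), CNX1 (adjusted p = 0.0612) and BIP2 (adjusted p = 0.0518).

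Heat shock genes were among those with the largest fitted rises with PIP2. Hsp70b rose 6.61-fold (log2 2.72 ± 0.16, SE, n = 3 arrays, limma adjusted p = 0.00903), and the small heat shock protein genes HSP17.6A and HSP17.6II rose by log2 2.71 ± 0.31 and 2.56 ± 0.29. The transcription factor gene RRTF1 rose by 2.65 ± 0.32, and BT2 and BT1, which encode BTB and TAZ domain proteins, by 2.56 ± 0.27 and 2.40 ± 0.30. The heat shock list medians were 1.99, 0.91 and 0.93 on PIP2 replicates 1 to 3, and the sugar starvation list lay higher on replicates 2 and 3, at 1.53 and 1.03. As plain means of the 3 arrays BT2 (2.58, SD 0.46) and RRTF1 (2.56, SD 0.76) lay above Hsp70b (2.45, SD 1.22). WRKY60 fell by 1.96 ± 0.13, the cation exchanger gene CHX16 fell by 1.93 ± 0.19, and FRK1, a receptor kinase gene used as a marker of pattern-triggered immunity, fell by 1.79 ± 0.19. TAT3 fell by 1.91 ± 0.21, and the nitrate transporter gene NRT2.5 fell by 1.71 ± 0.19.

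AT5G33355, whose probe lists more than 1 locus, AT1G76640, AT1G51802 and AT1G54050 completed the 10 largest rises with PIP2, from 2.40 for AT1G54050 to 2.48 for AT5G33355. AT4G12490, AT5G44575, AT5G28300, MLP423 and AT2G43620 completed the falls, from -1.92 for AT4G12490 to -1.65 for AT2G43620. Of 14 heat shock list members 11 rose and 0 fell, among them HSP18.2 (2.05 ± 0.13) and DREB2A (1.80 ± 0.11). The list passed camera (adjusted p = 1.72e-08) and fry (adjusted p = 0.0192), with adjusted p = 0.41 with an estimated correlation. In the jasmonate list 14 members rose and 3 fell (camera adjusted p = 9.22e-05, fry adjusted p = 0.0136, adjusted p = 0.307 with an estimated correlation). ANAC055, JAZ7 and JAZ9 rose by 1.67, 1.71 and 1.39, while TAT3, LOX2 and MYC4 fell. The other probes of LOX2 stood at -0.23, -0.04 and -0.11 against -0.81 for the probe used, and none of them passed (limma adjusted p from 0.405 to 0.826).

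In the salicylic acid list 9 of 29 members fell and 2 rose with PIP2 (camera adjusted p = 0.000636, fry adjusted p = 0.0192, adjusted p = 0.41 with an estimated correlation). PBS3, which acts in salicylic acid synthesis, fell by 1.31 ± 0.10, FMO1 fell by 1.11 ± 0.22 and ACD6 fell by 0.98 ± 0.11, while ROXY19 rose by 1.60 ± 0.09, with a second probe at 0.36 (limma adjusted p = 0.467). The list of pattern-triggered immunity markers passed camera upwards (adjusted p = 0.0349), with 7 members higher and 2 lower of 34 and medians of 0.10, -0.02 and 0.54 on replicates 1 to 3, but neither fry (adjusted p = 0.358) nor camera with an estimated correlation (adjusted p = 0.769). WRKY22 rose by 1.38 ± 0.09 and ZAT12 by 1.11 ± 0.10, whereas FRK1 and AT1G51890 fell. Cold and touch response genes COR47, TCH4 and COR15A rose by 1.25, 1.21 and 1.09 (5 of 10 list members higher, camera adjusted p = 0.00055, fry adjusted p = 0.00247, adjusted p = 0.307 with an estimated correlation). In the camalexin and indole glucosinolate list 5 of 21 members fell, among them MYB34, CYP83B1 and CYP79B2 at -1.12, -1.02 and -0.98 (camera adjusted p = 0.0349, fry adjusted p = 0.511, adjusted p = 0.769 with an estimated correlation), while the list's medians of -0.69, -0.64 and 0.11 on replicates 1 to 3 put replicate 3 on the other side of 0. In the sugar starvation list 6 of 10 members rose and 1 fell (camera adjusted p = 0.000476, fry adjusted p = 0.00781, adjusted p = 0.410 with an estimated correlation). Of 15 clock genes 6 rose with PIP2 (fry adjusted p = 0.0401, adjusted p = 0.410 with an estimated correlation), and of 14 abscisic acid genes 3 rose (camera adjusted p = 0.0132, fry adjusted p = 0.163, adjusted p = 0.769 with an estimated correlation).

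Photosynthesis genes, markers of mesophyll, had 5 of 38 members higher and 0 lower (camera adjusted p = 0.0284, fry adjusted p = 0.39, adjusted p = 0.769 with an estimated correlation), and LHCB1.1 rose by 0.74 ± 0.16, with other probes at 0.87 and, not past the test, 0.27 (limma adjusted p = 0.113). The list's medians on replicates 1 to 3 were 0.48, 0.13 and -0.32 with PIP2 and 0.31, -0.14 and -0.47 with PIP1, so the direction turned on replicate 3 of PIP2.

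In all 3997 genes changed with PIP2, 1680 higher and 2317 lower, 272 and 154 of them by at least 2-fold. The random replicate effect called 2313, and 0 genes were called without PIP2 replicate 1, 914 without PIP1 replicate 1, 1253 without PIP2 replicate 2 and 1535 without PIP2 replicate 3. Median centring in place of loess called 163 higher and 18 lower.

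**Figure D1:**
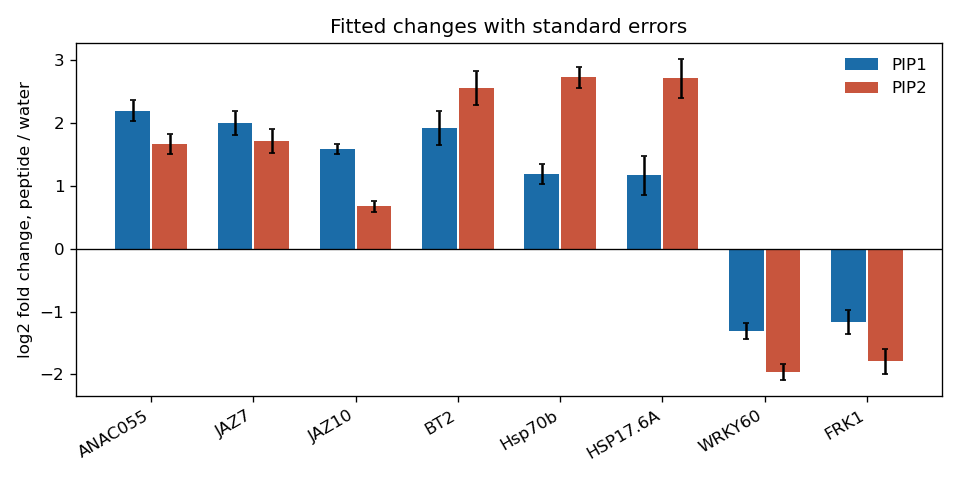
Fitted log2 fold change of peptide over water (vertical axis) for 8 genes, with PIP1 in blue and PIP2 in red and bars of 1 standard error. JAZ10 stood at 1.59 with PIP1 and 0.67 with PIP2, and Hsp70b at 1.19 and 2.72.

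No gene passed the test of PIP1 against PIP2, which were given at one dose and time. Genes were named here only where the sign was the same in 3 of 3 same-numbered pairs. Among these genes the smallest p values upwards belonged to PES1 (difference 1.18 ± 0.14), ORA59 (1.14 ± 0.15), the senescence-associated gene SAG13 (1.13 ± 0.10), JAZ10 (0.91 ± 0.12) and AT2G43530 (0.76 ± 0.11). Downwards they belonged to AT5G28630 (-1.18 ± 0.15), RVE2 (-0.90 ± 0.13), NUDT4 (-0.88 ± 0.10), AT5G18150 (-0.74 ± 0.10) and AT4G14740 (-0.70 ± 0.10). Each of these 10 genes had limma adjusted p = 0.594. With the replicate block, which uses the pairing, each passed, at adjusted p from 0.0303 for SAG13 to 0.0377 for AT2G43530. The block rewards the agreement between pairs by which the genes were picked, so their passing is not separate support.

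The block called 580 genes in this comparison, 302 higher with PIP1 and 278 lower, against 0 without it and 0 with a random replicate effect, where 1826 and 5278 genes had an unadjusted p under 0.05. The median 95% half-width of a difference was 0.35 and 0.20 with the block. Camera placed the jasmonate list higher with PIP1 (median difference 0.29, adjusted p = 4.15e-08) and the heat shock list lower (median -0.75, adjusted p = 5.47e-09). Neither passed with an estimated correlation (adjusted p = 0.162 and adjusted p = 0.609) or fry (adjusted p = 0.0528 and adjusted p = 0.493).

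**Figure D2:**
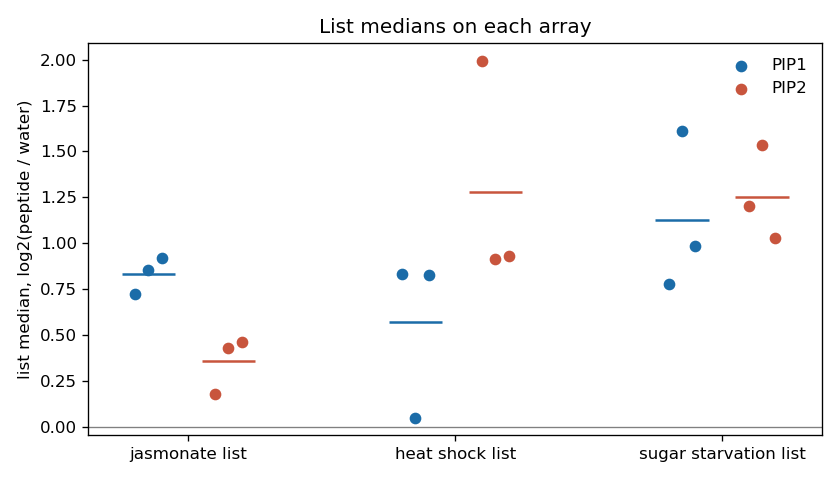
Median log2 ratio of peptide over water (vertical axis) of 3 gene lists on each array, with PIP1 in blue and PIP2 in red and lines at the mean of 3 arrays. The jasmonate medians were 0.72, 0.85 and 0.92 with PIP1 and 0.18, 0.43 and 0.46 with PIP2.

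Averaged over both peptides, BT2 rose 4.73-fold (log2 2.24 ± 0.20, SE, n = 6 arrays, limma adjusted p = 0.00537), and RRTF1 rose by 2.24 ± 0.23. ANAC055, ANAC072 and Hsp70b rose by 1.93, 1.89 and 1.96, each on 6 of 6 arrays, which was a condition for naming a gene by size. With the random replicate effect 3 of the 20 genes named by size were no longer called, HSP17.6A (adjusted p = 0.066), AT1G76640 (adjusted p = 0.0692) and AT5G48430 (adjusted p = 0.0506). WRKY60 fell by 1.64 ± 0.10, CHX16 fell by 1.61 ± 0.14, FRK1 fell by 1.48 ± 0.14 and TAT3 fell by 1.46 ± 0.15, each likewise on 6 of 6 arrays. Second probes of ROXY19 and TAT3 stood at 0.38 and -0.54 in the mean and did not pass (limma adjusted p = 0.291 and adjusted p = 0.0565). The precursor gene of PIP1, PREPIP1, rose by 0.65 ± 0.12 (adjusted p = 0.0211), but with the random replicate effect adjusted p = 0.142. PREPIP2 had a value of 0.82 ± 0.27 with PIP1 and -0.03 ± 0.27 with PIP2, and RLK7, which encodes a PIP1 receptor, -0.28 ± 0.14 and -0.27 ± 0.14, none of them past the test.

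In the jasmonate list 21 of 39 members rose and 3 fell (camera adjusted p = 4.64e-10, fry adjusted p = 0.0027, adjusted p = 0.112 with an estimated correlation). In the sugar starvation list 7 of 10 rose and 1 fell (camera adjusted p = 2.23e-05, fry adjusted p = 0.011, adjusted p = 0.416 with an estimated correlation). Its members BT2, DIN6 and DIN1 rose by 2.24, 1.66 and 1.25, and SAG13 fell. Among salicylic acid genes 9 of 29 fell and 2 rose (camera adjusted p = 0.0012, fry adjusted p = 0.0232, adjusted p = 0.416 with an estimated correlation), with UGT76B1 and PBS3 at -1.13 and -1.03. Of 15 clock genes 6 rose (camera adjusted p = 0.00632, fry adjusted p = 0.0297, adjusted p = 0.416 with an estimated correlation), led by PRR5 at 0.82 and RVE1 at 0.75. In the heat shock list 11 of 14 members rose and 0 fell (camera adjusted p = 5.00e-08, fry adjusted p = 0.0213, adjusted p = 0.416 with an estimated correlation). In the cold and touch response list 6 of 10 members rose and 0 fell (camera adjusted p = 0.0012, fry adjusted p = 0.00479, adjusted p = 0.362 with an estimated correlation). The abscisic acid list had 3 of 14 members higher (camera adjusted p = 0.00574, fry adjusted p = 0.0915, adjusted p = 0.646 with an estimated correlation), with a median of -0.06 on PIP1 replicate 2 and above 0 on the other arrays. The iron list, with 1 member higher and 2 lower of 15, passed fry downwards (adjusted p = 0.0309) but not camera (adjusted p = 0.182, and adjusted p = 0.646 with an estimated correlation). The lists of meristem, epidermis, vascular and root markers passed neither camera nor fry, while guard cell markers passed fry downwards (adjusted p = 0.0297) with TGG2 the 1 member called of 7, but not camera (adjusted p = 0.239, and adjusted p = 0.646 with an estimated correlation).

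The mean of both peptides changed 4546 genes, 1906 higher and 2640 lower. Only 742 of them were called with the random replicate effect, the sounder fit in simulation, while 0 were called without PIP1 replicate 1 or without PIP2 replicate 1, and median centring gave 371 higher and 72 lower. Camera called 7 lists here, but among 30 sign patterns of the arrays 22 gave at least 7, so its list calls are not told from chance. Fry called 8, with at most 2 in any other pattern, but these patterns break the pairing of the arrays, and the 3 that keep the replicate numbers together are too few to test chance.

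The responses to PIP1 and PIP2 correlated across 23126 genes (r = 0.787, rho = 0.771), where genes are not independent replicates. Simulated peptides with no effect gave r = 0.544 with a shared water RNA and 0.0606 with separate ones. In a simulation added after the results were seen, unchanged peptides on arrays paired as closely as the same-numbered arrays here, whose residuals correlated at 0.780, gave r = 0.801, so the correlation alone does not set the responses apart from the pairing. The 0.780 was taken without the dye term and holds any dye bias common to both peptides. With that term the consensus correlation was 0.701, at which r was not simulated. The observed covariance was 0.0722, against a simulated 0.0114 with shared water and 0.0169 with that pairing. The measured deviations of same-numbered arrays would bring 0.0242, which leaves 0.0478 of the covariance of the group means. Of the genes called with both peptides 65 were higher with both, against 4.90 for independent lists, 21 were lower with both, against 2.08, and 0 went in opposite directions. The values for independent lists leave out the pairing and any shared water RNA, so they are not what unchanged genes on these arrays would give. Arrays of different peptides and different replicate numbers correlated at 0.203 to 0.544, and those of one number at 0.690 to 0.834. The water channels of same-numbered arrays differed between the peptides with a median absolute deviation of 0.106, 0.0686 and 0.117 and the peptide channels with 0.262, 0.203 and 0.164, whereas the water channels of replicates 2 and 3, which lay on different slides, differed with 0.598 for PIP1 and 0.595 for PIP2. As the water RNA may have been shared, part of the excess may come from it.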

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

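The tests of the likeness of the responses and of the clock genes were chosen after the results were seen, as was the count of fry calls over sign patterns.

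Against 0 genes without the replicate block and 0 with the random replicate effect, the block called 580 genes as differing between the peptides. These included PES1 (1.18), ORA59 (1.14), SAG13 (1.13), JAZ10 (0.91), AT2G43530 (0.76), AT4G14740 (-0.70), AT5G18150 (-0.74), NUDT4 (-0.88), RVE2 (-0.90) and AT5G28630 (-1.18), as log2 differences of PIP1 minus PIP2. Swapping the peptides within any of the replicate numbers left 0 genes called by the block, but 4 arrangements are too few for a share under 0.05. Of the 580 genes, 210 were above 0 with both and larger with PIP2, 145 were below 0 with both and further below with PIP2, and 191 had opposite signs. Camera also set apart the lists of pattern-triggered immunity (median -0.0761), salicylic acid (0.18), jasmonate (0.29), camalexin (0.47), aliphatic glucosinolates (0.36), photosynthesis (-0.19), clock (-0.14), cold and touch (-0.27), heat shock (-0.75) and oxidative stress (0.21), while 0 lists were set apart with an estimated correlation and 0 with fry. Among the other splits of the arrays the highest count of lists was 14.

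Camera placed the jasmonate list higher and the heat shock list lower with PIP1 than with PIP2, but neither passed with an estimated correlation (adjusted p = 0.162 and adjusted p = 0.609) or fry (adjusted p = 0.0528 and adjusted p = 0.493). Without the replicate block 0 members were called, whereas the block called members such as JAZ10 and ORA59. An additive dye bias cancels from this comparison, since both peptides were in the same dye in each pair, so it does not account for the heat shock difference, which was -0.27 or lower in the 3 pairs. A wider spread on the PIP2 arrays would put the jasmonate list higher with PIP2, but it was higher with PIP1 in each pair, by at least 0.29. By median absolute deviation PIP2 was wider on replicate 1 (0.264 against 0.0734) and replicate 2 (0.127 against 0.0612). It was not wider on replicate 3 (0.234 against 0.270), so that pair does not bear on this argument. For the heat shock list a wider spread stays open, since scaling the spread brought the difference to -0.20, just inside the bound set in advance, although that scaling multiplied PIP1 replicate 2 by 2.38 and PIP1 replicate 3 by 0.54 and so did not follow the peptides. On replicate 3, without a wider PIP2 spread, the heat shock difference was still -0.27, but this is 1 pair.

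The responses to both peptides correlated at r = 0.787, no higher than the 0.801 simulated for unchanged peptides on arrays paired this closely. That simulation took its pairing without the dye term, and r was not simulated at the lower consensus correlation of 0.701 found with it. Water RNA shared within a replicate number does not account for all of the likeness, as arrays of different peptides and numbers correlated at 0.203 or more, nor does dye bias, as arrays in opposite dyes correlated at 0.210 or more. A change of the water plants against all peptide plants cannot be told apart from a shared response, since water RNA was the other channel on 100% of the arrays.

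The clock list passed camera upwards with PIP1 (0 of 15 members called, camera adjusted p = 0.0203, fry adjusted p = 0.197, adjusted p = 0.459 with an estimated correlation) and with PIP2 (6 of 15 higher, fry adjusted p = 0.0401, adjusted p = 0.410 with an estimated correlation). The sugar starvation list passed camera and fry with PIP1 (1 of 10 members higher, adjusted p = 0.273 with an estimated correlation) and PIP2 (6 higher and 1 lower, adjusted p = 0.410 with an estimated correlation). A different time of day of sampling might move morning and evening genes apart, and both medians lay above 0, the lower at 0.29. The sets held 5 genes each, with 2 and 3 called higher, so they cannot exclude such a difference. Dye bias is argued against by the sugar starvation medians, 0.78 or more on each of 6 arrays. A response to the peptides stays a hypothesis and a general difference of the water plants stays open.

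Among sign patterns of the arrays, PIP1 gave 89 genes and PIP2 3997 in 1 of 4 patterns each, with 0 in any other, and 4 patterns are too few for a share under 0.05. The difference gave 0 genes, a count that every split must reach, so the 10 of 10 splits that reached it (highest other 1) test nothing. The mean gave 4546 genes in 1 of 30 patterns with 0 in any other. Free patterns break the pairing of the arrays, and the 3 that keep the replicate numbers together are too few to exclude chance. Of list counts, the mean's 7 was reached by 22 of 30 patterns, with 13 the highest other, so chance is not excluded. The difference's 10 lists were reached in 3 of 10 splits (highest other 14), PIP1's 10 in 2 of 4 (highest other 12) and PIP2's 10 in 1 of 4 (highest other 6), which are too few for a share under 0.05.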

How the results depend on the processing

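The fits with replicates 2 and 3 only and with same-numbered arrays averaged first were chosen after seeing the data. Counts are given for PIP1, PIP2, the difference and the mean, against 89, 3997, 0 and 4546, where they moved by over 1.5 times, and the cause was not tested unless stated. The replicate block, which takes in the dye term, gave 6461, 11964, 580 and 12909 (inflated against water in simulation) and changed no direction of a named gene. The random replicate effect gave 29, 2313 and 742 for PIP1, PIP2 and the mean. The slide as a block without the dye term gave 950 for PIP1 and 7206 for the mean, and slide 1 alone 3421, 10651, 351 and 10415, while slide 2 holds 1 array per peptide and gives no test. On slide 1 the dye term is the same as the replicate block, so its counts against water share the block's fault. They are no measure of what slide 2 hides. Array weights gave 1616, 10362 and 9050 for PIP1, PIP2 and the mean. Median centring gave 0, 181 and 443, and scaling the spread 0, 0 and 0. For PIP1 alone, no dye term gave 139, no background correction 198, Agilent's processed signals 1, every probe separately 0, the deposited log2 ratios gave 176, and eBayes with trend and robust 0. In the next 3 settings the dye term was dropped as well. Only a peptide's own arrays gave 0 for PIP1 and 1485 for PIP2, replicates 2 and 3 alone gave 0, 0 and 539 for PIP1, PIP2 and the mean, and averaging same-numbered arrays first gave 88 for the mean.

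Leaving out 1 array gave 0 to 0 genes for PIP1, 0 to 4109 for PIP2, 0 to 0 for the difference and 0 to 3266 for the mean, and r from 0.623 to 0.851 for the responses across genes. List counts ranged over 5 to 13, 8 to 10, 8 to 11 and 7 to 9. Lists past the test were 10, 10, 10 and 7 with camera, 1, 0, 0 and 0 with an estimated correlation, and fry gave 4 for PIP1 and 0 for the difference. With the replicate block camera gave 10, 10, 10 and 7 lists, 0 in each contrast with an estimated correlation, and fry gave 4, 5, 0 and 5. Median centring gave 13 lists for the mean. Of named genes 1 reversed, RBCS1B in the mean, at -0.30 and at 0.10 with median centring (limma adjusted p = 0.747, not past the test). Slide 1 had fewer probes well above background than slide 2, which limits dim genes there.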

Other observations

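Gene families named by the array's own probe descriptions were chosen and tested after the results were seen. Of 20 families, 18 had at least 10 genes. Over both peptides 9 of them passed camera, 10 passed fry, 8 passed both and 0 passed camera with an estimated correlation, and the 8 are given here. Their counts of called genes come from the fit that leaves out the pairing of the arrays. In simulation with paired arrays that fit made 229 false calls of 427 for the mean. The families were not tested with the replicate number fitted. Cytosolic ribosomal protein genes were lower over both peptides, with 55 of 199 lower and 2 higher and a median of -0.23 (camera adjusted p = 9.70e-08, fry adjusted p = 0.00218, adjusted p = 0.0826 with an estimated correlation). Protein disulfide isomerases and endoplasmic reticulum chaperones had 10 of 18 genes lower and 0 higher, with a median of -0.47 (camera adjusted p = 5.35e-06, fry adjusted p = 0.00882, adjusted p = 0.297 with an estimated correlation). Pentatricopeptide repeat genes had 80 of 337 lower and 4 higher, with a median of -0.14 (camera adjusted p = 8.97e-09, fry adjusted p = 0.0165, adjusted p = 0.379 with an estimated correlation). With PIP2 84 were lower (median -0.22), whereas with PIP1 0 were called (median -0.06, fry adjusted p = 0.223). The difference between the peptides passed camera (adjusted p = 6.29e-12) but neither fry (adjusted p = 0.425) nor camera with an estimated correlation (adjusted p = 0.477). Aquaporin genes had 5 of 16 higher and 0 lower (camera adjusted p = 0.0151, fry adjusted p = 0.00839, adjusted p = 0.297 with an estimated correlation). Leucine-rich repeat receptor kinase genes had 24 of 115 lower and 4 higher (camera adjusted p = 7.42e-05, fry adjusted p = 0.0165, adjusted p = 0.379 with an estimated correlation). TIR-NBS-LRR resistance genes had 11 of 45 higher and 3 lower (camera adjusted p = 0.0421, fry adjusted p = 0.0108). Proteasome subunit genes had 8 of 42 lower and 0 higher (camera adjusted p = 0.0151, fry adjusted p = 0.00797), and trehalose synthase and phosphatase genes 4 of 14 higher and 1 lower (camera adjusted p = 0.0421, fry adjusted p = 0.00746). The last 3 families each had adjusted p = 0.297 with an estimated correlation. With PIP1 alone 0 or 1 gene was called in each of the 8 families, where 0.38% of all genes were called. The 8 medians with PIP1 lay on the same side of 0 as with PIP2, which choosing the families on the mean of both peptides favours. Single PIP1 arrays lay on the other side. These were replicate 1 for the TIR-NBS-LRR genes (-0.036) and replicate 2 for the receptor kinase (0.004) and trehalose (-0.013) genes. Fry with PIP1 passed for the ribosomal, proteasome, aquaporin and trehalose families (adjusted p = 0.0109, 0.0139, 0.0109 and 0.0235). In the others its adjusted p lay from 0.0553 to 0.223, and 0 families passed camera with an estimated correlation.

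Among genes with the largest paired differences, chosen after their values were seen, the potassium transporter gene HAK5 stood 2.28 higher with PIP1 than with PIP2 (block adjusted p = 0.0316), and Hsp70b stood at -1.54 (block adjusted p = 0.0402). RNS1, a ribonuclease gene, stood 1.75 higher, and the nitrate reductase gene NIA1 at -1.13. None of these differences passed without the block (limma adjusted p from 0.594 to 0.643). HAK5 and RNS1 passed against water with neither peptide (limma adjusted p from 0.320 to 0.501).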
